A study of Mus musculus with 8 samples.

How the data were processed

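RNA sequencing was done on mouse full-grown oocytes from ovaries, with 2 libraries in each of 4 groups: H2A.Z control, H2A.Z DKO as labelled, Mll2 WT and Mll2 KO. Each library was prepared from a pool of about 20 oocytes with a SMART-Seq cDNA kit for low input and the Nextera XT kit, starting from 200 pg of cDNA. The values used are the whole-number raw counts per gene symbol deposited by the authors, without normalisation, for 35976 symbols, of which 8787 had 0 counts in every library. Per the submitters' processing notes, Trim Galore 0.6.4, STAR 2.7.3 and RSEM 1.3.1 were used with genome build mm10. The role of each tool, the annotation and whether estimates were rounded to whole numbers are not given in the sources used here. Totals ran from 20309233 to 30087863 counts per library.

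The groups were those of the sample labels, and no library was left out. Replicate numbers were not treated as pairs, because the labels name no shared litter or day and the differences between replicates correlated across genes by only 0.04 and -0.022 between control and mutant of a line. Counts were analysed in R 4.3.3 with edgeR 4.0.16. All 8 libraries entered one fit with 4 group means, genes were kept with filterByExpr by group (16847 genes), libraries were scaled by the trimmed mean of M-values (TMM), and the quasi-likelihood test was run with robust estimation. The fit had 4 residual degrees of freedom, a common dispersion of 0.0152 and a median of 11.8 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 are those called higher or lower. The contrasts were DKO as labelled minus H2A.Z control, Mll2 KO minus Mll2 WT, the difference between those effects (the interaction contrast), and H2A.Z control minus Mll2 WT. The SE of a log2 fold change was derived from the quasi-likelihood F statistic. Log2 CPM for correlations and principal components used a prior count of 2. Normalised CPM divide by the library total times the TMM factor.

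Named genes were chosen by a rule. It took the targeted genes H2afz, H2afv and Kmt2b, plus Kmt2d, in every library. It took the 12 genes with the largest log2 fold change in each direction of each mutant comparison, if called, at 10 CPM or more in the higher group and with both mutant libraries on the same side of both controls, leaving out predicted, clone, pseudogene and microRNA symbols. It took up to 4 called members of each list with the smallest p. From the interaction contrast it took the 6 largest called differences each way among genes at 10 CPM or more in any group. The 6 genes with the largest shared change each way were taken among those at 10 CPM or more in the higher group of each line. Both choices left out the same kinds of symbols. Any called member of the lists for H3K4 methylation, H2A.Z deposition, meiotic resumption and the APC/C was also allowed. The rule, the comparisons, the 29 gene lists and all alternatives except the offsets named at the end were set before the data were examined.

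The lists cover zona pellucida and oocyte-secreted factors, oocyte transcription factors, the subcortical maternal complex and maternal-effect genes, maternal mRNA storage, translation and decay, meiotic resumption, the APC/C and spindle checkpoint, spindle and segregation genes, meiotic cohesin and recombination, and H3K4 methylation. They further cover H2A.Z deposition, histone variants, core histones, DNA methylation and KRAB repression, Polycomb components, developmental regulators, genes of the 2-cell stage, imprinted genes, the p53 pathway, the stress response, heat shock, oxidative phosphorylation, ribosomal proteins, glycolysis, cholesterol synthesis and spermatogenic genes. Markers of granulosa and cumulus cells, of theca and stroma, and of blood, immune and endothelial cells were included as signs of other cell types. Of these, 28 had at least 5 tested members, and the list of mitochondrially encoded genes had none in the table. Lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the 28 lists, and again with an estimated correlation and with fry. Members called over all genes and members called when the p-values were adjusted over the list alone were counted. Genes with no counts in a group were set at a floor of 3 counts over the group when a list median was recomputed at that bound, and ratios on few counts carry exact binomial 95% intervals.

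Overlaps of calls were tested with Fisher's exact test, two-sided. Fold changes were correlated across genes without a p-value, since genes are not independent. For fold change against expression level, 10 bins of genes were set from the mean log2 CPM of the controls of the other line. Gene positions came from RefSeq on mm10 for 33506 symbols, and GC content and transcript length from GENCODE M21 for 26763 symbols, 14638 of them tested. Copies of H2afz and H2afv were searched with BLAST 2.17.0 at 90% identity or more over at least 200 bases, and only H2afz had any. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

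The procedure was tested on simulated data made from the counts with 200 genes changed. Far more genes were called in the data, and each simulated gene had the same dispersion in all groups, so the rates below need not hold for the data. For the comparison of libraries labelled DKO with controls, 20.9%, 61.2% and 81.8% of genes changed 1.5-, 2- and 4-fold were recovered, and 6.84% of calls were unchanged genes. For Mll2 KO the recovery was 23.9%, 59.7% and 84.8%, with 6.67% unchanged, and for the interaction contrast 3%, 31.3% and 66.7%, with 6.94% unchanged. For the controls it was 25.4%, 64.2% and 92.4%, with 8.33% unchanged. The list test found the 1 list shifted by 0.8 on the log2 scale and called 0 of the others. Genes were simulated independently, so this cannot check the preset correlation between genes. The shift was also larger than the median of every list called in the data except the 2-cell list.

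The alternatives were relative log expression factors, library size alone, no filter on low counts, a mean of at least 5 CPM, an added limit of 1 on the absolute log2 fold change, a replicate block, each line fitted alone, DESeq2 1.42.0, the other list tests, bins from all 8 libraries, and omission of each library in turn. Offsets for GC content and transcript length were added after the data had been seen.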

Results

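Polyadenylated RNA was sequenced from mouse full-grown oocytes, the cells that have completed growth in the ovary and hold the stored transcripts used by the early embryo. Each of the 8 libraries was made from a pool of about 20 oocytes freed of the zona pellucida, with 200 pg of amplified cDNA taken into library preparation. There were 4 groups of 2 libraries. The H2A.Z control group and the group labelled as a double knockout (DKO) of both H2A.Z genes formed the H2A.Z line, and the Mll2 wild-type (WT) and Mll2 knockout (KO) groups formed the Mll2 line. H2A.Z is a variant of histone H2A found at promoters, and MLL2 is a methyltransferase acting on lysine 4 of histone H3. The total counts were 20309233 and 25186157 in the H2A.Z controls, 24948989 and 23777538 in the libraries labelled DKO, 29002828 and 30087863 in the Mll2 WT libraries, and 26899988 and 26328854 in the Mll2 KO libraries. Between 21077 and 22212 genes had at least 1 count per library, and 16847 genes were tested. Replicates correlated across genes on the log2 scale with r from 0.984 to 0.989. Their spread relative to counting error (chi-square per degree of freedom over genes) was 4.75 in the H2A.Z controls, 6.44 under the DKO label, 12.8 in Mll2 WT and 39.3 in Mll2 KO, so the Mll2 KO pair was the most variable. The first principal component took up 49.2% of the variance and separated the H2A.Z line from the Mll2 line. The second took up 26.6% and separated the knockout from the control libraries in both lines, while the Mll2 KO libraries lay apart on the first, at 68.7 and 92.3. Values are means ± SD of the 2 libraries of a group, in CPM (counts scaled to a common library total), and fold changes carry their standard error (SE). Adjusted p-values measure only the spread between these libraries, since the labels do not say that replicates came from separate animals. The fit shared 1 spread per gene among all groups. Adjusted p-values can therefore be too small for Mll2 KO and too large for the H2A.Z line. With each line fitted alone, 3466 genes and not 5158 were called in Mll2 KO, and 6777 and not 5198 under the DKO label. Fitting a line alone also changed the filter and scaling. Counting intervals cover counting error only.

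The targeted genes were examined first, in every library, on genome build mm10. H2afz (chromosome 3, 137864487 to 137866922), which encodes H2A.Z.1, was higher and not lower under the DKO label, with 23.9 and 30 CPM in the controls and 322 and 317 CPM in the libraries labelled DKO. The log2 difference was 3.56 ± 0.14 (11.8-fold, edgeR adjusted p = 6.63e-10). H2afv (chromosome 11, 6427226 to 6444511), which encodes H2A.Z.2, moved the same way, from 107.9 and 107.2 CPM to 285 and 294 CPM (log2 1.43 ± 0.10, adjusted p = 1.73e-07). The values are counts over whole genes, so transcripts from a modified allele that keeps other exons are counted with intact ones, and the exons removed are not given in the labels. In the Mll2 line, H2afz measured 7.04 and 7.09 CPM in WT and rose to 19.4 and 15 CPM in KO (log2 1.28 ± 0.15, adjusted p = 1.21e-05). H2afv measured 86.8 and 88.2 CPM in WT and 93.7 and 106.1 CPM in KO, a log2 difference of 0.19 ± 0.10 that did not pass the test (adjusted p = 0.165). Kmt2b (chromosome 7, 30568855 to 30589056) fell in Mll2 KO from 41.9 and 42.4 CPM to 8.73 and 9.28 CPM (log2 -2.23 ± 0.15, adjusted p = 2.72e-08). In the H2A.Z line Kmt2b rose from 13.7 and 15.4 CPM to 20.4 and 20.6 CPM (log2 0.49 ± 0.15, adjusted p = 0.018), a call that was lost without H2A.Z control 1 or 2, DKO 1 or 2, or Mll2 WT 2 (adjusted p = 0.153, 0.0601, 0.0833, 0.0853 and 0.132). Kmt2d (chromosome 15, 98831669 to 98874077), another methyltransferase gene for which the name Mll2 has been used, measured 87.6 and 80 CPM in Mll2 WT and 80 and 96.9 CPM in KO (log2 0.08 ± 0.12, adjusted p = 0.652). Kmt2d rose in the libraries labelled DKO, from 36.4 and 39.5 CPM to 54.1 and 53.8 CPM (log2 0.51 ± 0.12, adjusted p = 0.00565), which was not past the threshold without H2A.Z control 1 or Mll2 WT 2 (adjusted p = 0.071 and 0.0532).

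**Figure D1:**
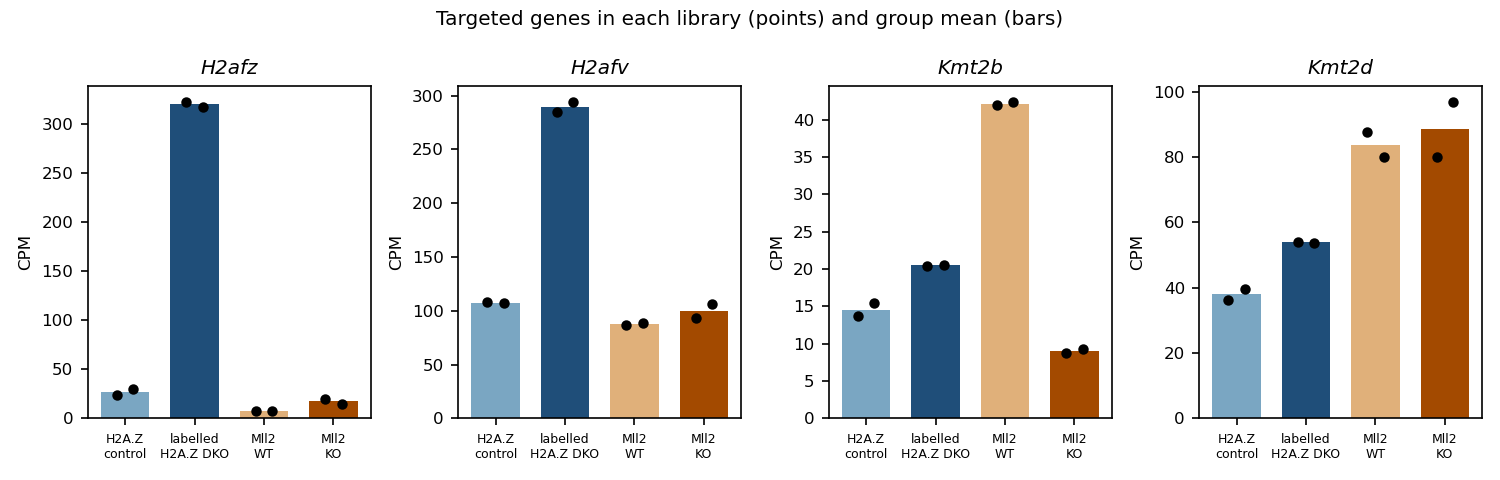
CPM of H2afz, H2afv, Kmt2b and Kmt2d, with bars at group means and points at the 8 libraries. H2afz and H2afv are highest in the libraries labelled DKO (means 319.8 and 289.6 CPM), and Kmt2b is lowest in Mll2 KO (mean 9 CPM).

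The comparison of libraries labelled DKO with H2A.Z controls addressed which oocyte transcripts differ when both H2A.Z genes are targeted. Because H2afz and H2afv went against the label, each direction here is that of the label and not of a loss of H2A.Z transcripts. Mt1 (chromosome 8, 94178883 to 94180327), a metallothionein that binds zinc and copper, rose from 5.78 ± 3.38 to 1319 ± 89.1 CPM (log2 7.87 ± 0.34, 234-fold, adjusted p = 6.77e-07). Transcripts typical of the embryo at its activation also rose: Zscan4c and Zscan4d from 1.41 ± 0.13 to 28.2 ± 5.72 CPM and from 7.90 ± 1.70 to 129.5 ± 12.6 CPM. Their log2 differences were 4.33 ± 0.31 and 4.04 ± 0.34 (adjusted p = 1.83e-07 and 3.58e-05). Usp17lb, a deubiquitinase gene of a repeated family, rose from 0.629 ± 0.01 to 14.1 ± 1.68 CPM (log2 4.47), and Pramef25, of the PRAME family, from 0.523 ± 0.06 to 11.9 ± 1.74 CPM (log2 4.51). Zc4h2, an X-linked zinc finger gene, fell from 11.2 ± 1.25 to 0.276 ± 0.01 CPM (log2 -5.32 ± 0.37, adjusted p = 1.5e-07). The count table has 1 value per gene symbol, and reads shared between near-identical members of the Zscan4, Usp17l and Pramef families cannot be assigned with certainty.

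The other 7 genes with the largest increases under the DKO label spanned several functions. Prrx1, a homeobox gene of mesenchyme, rose from 0.364 ± 0.29 to 14.5 ± 0.70 CPM (log2 5.39 ± 0.41, adjusted p = 3.14e-07). Fshr, the receptor of follicle-stimulating hormone, rose from 0.945 ± 0.49 to 18.8 ± 0.12 CPM (log2 4.36 ± 0.30, adjusted p = 1.5e-07). The list of granulosa and cumulus cell markers to which it belongs had a median log2 difference of -0.04 and was not past the threshold. Fshr rose in Mll2 KO as well, from 0.793 ± 0.28 to 7.47 ± 0.32 CPM (log2 3.23 ± 0.30, adjusted p = 1.05e-06), where the list had a median of 0.80 and was not past the threshold either. Hmgn3, a nucleosome-binding protein gene, rose from 6.59 ± 0.77 to 119.8 ± 3.56 CPM (log2 4.18 ± 0.22, adjusted p = 3.46e-08). Stambpl1, a deubiquitinase gene, Trim6, a ubiquitin ligase gene, and Serpinb1a, a protease inhibitor gene, had log2 differences of 4.47, 4.34 and 3.77. Tmsb4x, which encodes an actin-binding peptide, rose by 3.78 ± 0.61 (adjusted p = 0.00165, and 0.0564 without either Mll2 KO library, which enter through the shared spread), with 17.5 ± 11.7 CPM in the libraries labelled DKO. Of the largest decreases, Commd8, a COMM-domain gene, fell from 33.8 ± 0.97 to 2.43 ± 0.12 CPM (log2 -3.80 ± 0.44, adjusted p = 0.000277). Ckap2l, a spindle protein gene, fell from 28.4 ± 1.17 to 3.25 ± 1.98 CPM (log2 -3.11 ± 0.27, adjusted p = 1.29e-06). Nicn1, a subunit gene of tubulin polyglutamylase, fell to 1.26 ± 0.84 CPM (log2 -3.64). Aamdc fell to 3.11 ± 0.51 CPM (log2 -3.04) and the ubiquitin ligase gene Rnf13 to 3.94 ± 0.93 CPM (log2 -2.96). The remaining 6 were Enpp4 (log2 -3.57), Tmem205 (log2 -3.47), Efcab7 (log2 -3.33), the zinc finger genes Zfp74 (log2 -3.09) and Zfp959 (log2 -2.99), and Fez2 (log2 -3).

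In all, 3269 genes were higher and 1929 lower in the libraries labelled DKO, of which 981 and 987 changed more than 2-fold, 326 and 364 more than 4-fold, and 103 and 115 more than 8-fold. The median log2 difference of all tested genes was 0.12 with the scaling used, 0.08 with relative log expression factors and 0.00 with library size alone. The share of calls that were higher was 62.9%, 56.9% and 45.5%, so medians of the lists past the threshold are given here also relative to all genes. With the H2A.Z line alone the median was 0.006 and 48.6% of calls were higher. Without Mll2 KO 1 or 2 the median was 0.004 and 0.003, so the shift depended on which libraries were scaled together. List members higher and lower were not counted with the line alone. The number higher was 1637 and 1496 without H2A.Z control 1 or 2, 1634 and 1890 without DKO 1 or 2, and 1820 without Mll2 WT 2. The number lower was 1176 and 1146 without either control, 1115 and 1191 without either library labelled DKO, and 3381 and 3378 without Mll2 KO 1 or 2, which enter through the shared scaling and spread.

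Among the lists fixed beforehand, cytosolic ribosomal protein genes were the most uniform under the DKO label: 49 of 80 rose and 0 fell (54 and 0 adjusted over the list alone). Their median log2 difference of 0.40 was 0.28 above that of all genes (camera adjusted p = 4.21e-10, and adjusted p = 0.807 with an estimated correlation). Rps25, Rpl41 and Rps29 rose by 0.69, 0.67 and 0.64 on the log2 scale. Of 31 genes of the 2-cell stage and zygotic genome activation in the count table, 18 were tested, and of these 10 rose and 3 fell (12 and 3 adjusted over the list alone). A member with few counts in the controls was tested only if other libraries held enough. The filter itself can therefore raise the number higher and the median of this list in either mutant comparison. The median was 3.80, 3.68 above all genes, or 2.72 with Usp17la, which had no counts in the controls, held at 3 counts over the group (adjusted p = 0.00532, and adjusted p = 0.656 with an estimated correlation). The summed CPM of this list did not rise with it, at 904 and 904 in the controls and 892 and 974 under the DKO label. Of 15 histone variant and linker histone genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.65, 0.53 above all genes, adjusted p = 0.00589, and adjusted p = 0.61 with an estimated correlation). These include H2afz and H2afv themselves and H3f3b, a gene of histone H3.3, which rose from 1414 ± 59.2 to 2248 ± 35 CPM (log2 0.67). H2afy2, a macroH2A gene, fell (log2 -3.75 ± 0.55). Of 26 genes of DNA methylation, KRAB repression and H3K9 methylation, 12 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.37, 0.24 above all genes, adjusted p = 0.00773, and adjusted p = 0.736 with an estimated correlation). Among them Zfp445, a zinc finger gene of imprint maintenance, rose by 1.20, the corepressor gene Trim28 by 0.96, the H3.3 chaperone gene Daxx by 0.83 and the heterochromatin protein gene Cbx1 by 0.63 on the log2 scale. Of 28 Polycomb genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.30, 0.18 above all genes, adjusted p = 0.0274, and adjusted p = 0.78 with an estimated correlation). Those that rose included Jarid2 (log2 0.75), Cbx2 (log2 0.99), Phf1 (log2 0.92) and Bap1 (log2 0.64). Without DKO 1 or Mll2 WT 2 the Polycomb list had an adjusted p of 0.0935 or 0.0849.

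Of 80 nuclear-encoded oxidative phosphorylation genes, 30 rose and 7 fell under the DKO label (32 and 8 adjusted over the list alone). The median of 0.21 was 0.08 above all genes (adjusted p = 0.0106, and adjusted p = 0.837 with an estimated correlation). Cox5b, Uqcrq and Ndufa6 rose by 0.84, 0.76 and 0.75 on the log2 scale and Ndufv3 fell by 1.47. This list had adjusted p-values of 0.106, 0.122, 0.0891 and 0.0874 without DKO 2, Mll2 WT 2, Mll2 KO 1 and Mll2 KO 2, and 0.104 with the H2A.Z line fitted alone. Spindle, kinetochore and chromosome segregation genes went the other way, with 3 of 40 higher and 13 lower (4 and 13 adjusted over the list alone). Their median of -0.13 was 0.26 below all genes (adjusted p = 0.00773, 0.0691 without H2A.Z control 1, and adjusted p = 0.807 with an estimated correlation). Aurkb, the kinase of the chromosomal passenger complex, fell from 14.2 ± 1.76 to 3.94 ± 0.95 CPM (log2 -1.85 ± 0.20, adjusted p = 6.79e-06). Tacc3 and Kif2c, which act on spindle microtubules, fell by 0.57 each, while Cenpa, the centromeric histone gene, rose by 0.51. With library size alone as the scaling, the numbers higher and lower were 34 and 1 for ribosomal protein, 7 and 2 for DNA methylation and KRAB, 8 and 0 for Polycomb, 19 and 10 for oxidative phosphorylation and 1 and 17 for spindle genes. None of these 7 lists was past the threshold with an estimated correlation, where 1 list had an unadjusted p under 0.05. With fry the spindle list was not past the threshold either (fry adjusted p = 0.125).

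The other 21 lists were not past the threshold in the libraries labelled DKO, with adjusted p from 0.0926 to 0.968. The meiotic cohesin, synapsis and recombination list (adjusted p = 0.112) was past it without H2A.Z control 2 (adjusted p = 0.0275). Of 26 genes of H3K4 methylation and demethylation, 10 were higher and 2 lower (10 and 2 adjusted over the list alone). They included the methyltransferase genes Setd1b (log2 1.08, from 5.05 to 10.7 CPM) and Setd1a (log2 0.89, from 11 to 20.5 CPM) and the shared subunit gene Dpy30 (log2 0.54). Of 26 genes of H2A.Z deposition and removal, 8 were higher and 2 lower (8 and 3 adjusted over the list alone). Epc2, Epc1 and Ep400 of the TIP60 complex rose by 1.08, 0.73 and 0.62 on the log2 scale, and Vps72, whose product binds H2A.Z, fell by 0.78. APC/C and spindle checkpoint genes divided 5 higher and 4 lower of 29 (5 and 4 adjusted over the list alone). The APC/C subunit gene Cdc26 fell from 52.7 ± 0.53 to 20.8 ± 0.15 CPM (log2 -1.34 ± 0.14, adjusted p = 4.62e-06). The APC/C activator gene Cdc20 fell from 105.9 ± 6.54 to 71.1 ± 3.24 CPM (log2 -0.58 ± 0.11, adjusted p = 0.000945). Of 30 meiotic resumption and M-phase kinase genes, 4 were higher and 2 lower (1 and 1 adjusted over the list alone). Developmental regulators had 15 higher and 4 lower of 43 (15 and 4 adjusted over the list alone), among them Pax6 (log2 2.21, from 1.02 to 4.73 CPM) and Gata4 (log2 1.52, from 2.43 to 7.06 CPM). With library size alone as the scaling, the medians of the zona pellucida, meiotic resumption, APC/C, p53, stress response and spermatogenic lists changed sign. The numbers higher and lower were then 1 and 5 for the APC/C, 5 and 4 for H2A.Z deposition, 7 and 3 for H3K4 methylation, 10 and 4 for developmental regulators and 1 and 3 for meiotic resumption.

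For the remaining lists in the libraries labelled DKO, the numbers higher and lower, with those adjusted over the list alone in brackets, were as follows. They were 5 and 1 of 15 zona pellucida and oocyte-secreted factors (5 and 1), 7 and 0 of 17 oocyte transcription factors (7 and 0). They were 8 and 2 of 28 subcortical maternal complex and maternal-effect genes (8 and 3), and 8 and 2 of 30 maternal mRNA storage and decay genes (8 and 2). Meiotic cohesin, synapsis and recombination genes had 2 and 4 of 29 (2 and 4), replication-dependent core histone genes 3 and 1 of 24 (1 and 0), imprinted genes 9 and 3 of 29 (9 and 3), and spermatogenic genes 3 and 2 of 21 (3 and 2). The p53 pathway list had 7 and 4 of 26 (8 and 4), the integrated stress and unfolded protein response 6 and 3 of 20 (6 and 3), the heat shock response 3 and 1 of 14 (3 and 1), glycolysis 2 and 0 of 17 (0 and 0), and cholesterol synthesis 0 and 4 of 21 (0 and 3). Markers of other cell types had 2 and 2 of 16 for granulosa and cumulus cells (2 and 2), 1 and 0 of 9 for theca and stroma (1 and 0), and 1 and 0 of 7 for blood, immune and endothelial cells (1 and 0). Several of these splits depended on the scaling. They were, with library size alone, 5 and 7 for the subcortical maternal complex list, 2 and 4 for the zona pellucida list (3 and 3 with relative log expression factors), 2 and 0 for oocyte transcription factors, 3 and 3 for mRNA storage and decay, and 2 and 8 for meiotic cohesin and recombination. They were 2 and 2 for core histone genes and 2 and 3 for spermatogenic genes. Examples were the apoptosis gene Pmaip1, which rose from 0.354 ± 0.06 to 5.78 ± 1.86 CPM (log2 4 ± 0.48, adjusted p = 2.24e-05), the oocyte maturation genes Omt2a and Omt2b (log2 0.54 and 0.50), and the protamine gene Prm2 (log2 1.75). The list of mitochondrially encoded genes could not be tested, since 0 of its 13 genes were in the count table.

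The Mll2 KO libraries were compared with Mll2 WT to learn which oocyte transcripts differ without MLL2. Among the genes that fell most, Tex15, needed for meiotic recombination in male germ cells, went from 219.8 ± 40.9 to 8.10 ± 2.42 CPM (log2 -4.76 ± 0.20, adjusted p = 2.46e-09). Ccdc172, a coiled-coil gene, fell from 44.9 ± 1.87 to 0.841 ± 0.19 CPM (log2 -5.73 ± 0.19, adjusted p = 2.4e-11). Gli3, a transcription factor gene of Hedgehog signalling, fell from 29.7 ± 14 to 0.606 ± 0.24 CPM (log2 -5.60 ± 0.50, adjusted p = 4.08e-05). The X-linked genes Xlr3c, Xlr4b, Fmr1nb and Tmem47 fell by 5.45, 4.61, 5.99 and 4.98 on the log2 scale, from between 18.6 and 25.1 CPM in WT to under 1 CPM in KO. Mt1 rose again, from 1.78 ± 0.60 to 1174 ± 4.03 CPM (log2 9.36 ± 0.37, 657-fold, adjusted p = 1.52e-07). Krt79, a keratin gene, rose from 1.24 ± 0.12 to 39.7 ± 9.83 CPM (log2 5 ± 0.26, adjusted p = 2.15e-09).

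A pair of genes had so few KO counts that only a ratio can be given: Hnrnph2, an X-linked splicing regulator gene, was 197-fold lower with a counting interval of 76.5 to 724. The zinc finger gene Zfp512 was 102-fold lower with an interval of 46.7 to 279. The other large decreases were in Commd8 (log2 -5.92 ± 0.55), Zfp788 (log2 -5.65 ± 0.32) and Efcab7 (log2 -4.69 ± 0.32). Hnrnph2 and Commd8 had no counts in Mll2 KO 2, so without Mll2 KO 1 their fitted log2 values were -11.44 and -12.28, which are not estimates of size. Of the large increases, Prpf39, a component of the U1 small nuclear ribonucleoprotein, rose from 28.8 ± 3.94 to 265.3 ± 61.8 CPM (log2 3.2 ± 0.16, adjusted p = 2.12e-09). Cdc5l, a component of the spliceosome, rose from 1.12 ± 0.28 to 13.4 ± 3.75 CPM (log2 3.57 ± 0.28, adjusted p = 1.69e-07). Ntf3, which encodes neurotrophin-3, rose from 0.429 ± 0.23 to 10 ± 1.14 CPM (log2 4.53 ± 0.42). Ptgds, a prostaglandin D synthase gene, rose from 4.39 ± 0.46 to 46.3 ± 6.25 CPM (log2 3.4 ± 0.19), and Ccl2, a chemokine gene, from 5.53 ± 0.48 to 34.7 ± 16.7 CPM (log2 2.65 ± 0.29). Cldn34d, a claudin gene, Terf2ip, of the telomere-binding shelterin complex, the protein kinase C gene Prkcb, Mplkip, and Pira6, an immunoglobulin-like receptor gene, rose by 3.33, 2.66, 2.4, 2.18 and 2.17 on the log2 scale. The call of Pira6 (adjusted p = 0.0213) was lost without any of Mll2 WT 1 or 2 or Mll2 KO 1 or 2 (adjusted p = 0.0745, 0.127, 0.154 and 0.0988).

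In Mll2 KO, 2428 genes were higher and 2730 lower, with 996 and 1134 changed more than 2-fold, 321 and 441 more than 4-fold, and 98 and 204 more than 8-fold. The median log2 difference of all genes was 0.02 with the scaling used and 0.14 with library size alone, and 47.1% and 62.9% of calls were higher. The number higher was 1270 and 990 without Mll2 WT 1 or 2, and the number lower was 1691 without Mll2 WT 2. With the Mll2 line fitted alone, 1636 were higher and 1830 lower, and 66.7% of the calls were kept.

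Meiotic cohesin, synapsis and recombination genes fell together in Mll2 KO: 15 of 29 fell and 2 rose (16 and 3 adjusted over the list alone). The median log2 difference was -0.69, 0.71 below all genes (camera adjusted p = 2.53e-05, and adjusted p = 0.704 with an estimated correlation). Beside Tex15, Tex12 of the synaptonemal complex central element fell from 71.3 ± 15 to 13.1 ± 3.43 CPM (log2 -2.45 ± 0.18, adjusted p = 6.83e-08). Tex11, which acts in crossover formation, fell from 45.6 ± 6.04 to 18.9 ± 1.19 CPM (log2 -1.27 ± 0.14, adjusted p = 1e-05). Majin, which ties telomeres to the nuclear envelope in meiosis, was 138-fold lower with a counting interval of 24.4 to 5500, on 1 count in KO. Of 14 heat shock genes, 9 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.39, adjusted p = 0.00184, and adjusted p = 0.704 with an estimated correlation). Hspa1b fell from 14.7 ± 3.64 to 1.26 ± 0.40 CPM (log2 -3.53 ± 0.27) and Hspb1 from 4.16 ± 1.11 to 0.387 ± 0.02 CPM (log2 -3.41 ± 0.33), with Hspa4l and Hsp90ab1 lower by log2 -1.18 and -0.69. Of 15 genes of the zona pellucida list, 8 fell and 0 rose (9 and 0 adjusted over the list alone, median -0.31, adjusted p = 0.00184, and adjusted p = 0.737 with an estimated correlation). Only 3 fell with library size alone as the scaling. Its members with the smallest p were Oosp3, an oocyte-secreted protein gene, from 1848 ± 83.1 to 1074 ± 84.2 CPM (log2 -0.78 ± 0.11, adjusted p = 6.87e-05), Kit, the receptor of stem cell factor (log2 -0.54), and Oosp2 (log2 -0.48).

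A pair of the cell division lists was past the threshold in Mll2 KO, each with more genes lower than higher. Of 40 spindle, kinetochore and segregation genes, 16 fell and 1 rose (16 and 2 adjusted over the list alone, median -0.18, adjusted p = 0.00741, and adjusted p = 0.737 with an estimated correlation). They included Prc1 (log2 -0.81), Tacc3 (log2 -0.63), the condensin gene Smc4 (log2 -0.57) and the topoisomerase gene Top2b (log2 -1.06). Of 29 APC/C and spindle checkpoint genes, 12 fell and 4 rose (12 and 4 adjusted over the list alone, median -0.24, adjusted p = 0.0158, and adjusted p = 0.704 with an estimated correlation). Among those that fell were the APC/C subunit genes Cdc16, from 32.5 ± 1.04 to 13.3 ± 0.86 CPM (log2 -1.29 ± 0.15, adjusted p = 1.57e-05), and Anapc16 (log2 -0.66). The checkpoint kinase gene Bub1b fell from 1085 ± 1.99 to 716.3 ± 30.2 CPM (log2 -0.60 ± 0.10, adjusted p = 0.000358), and the APC/C inhibitor gene Fbxo5 by 0.59 on the log2 scale. With library size alone, 8 spindle genes and 6 APC/C genes were lower and 4 of each were higher.

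A pair of lists rose in Mll2 KO. Of 80 cytosolic ribosomal protein genes, 46 rose and 2 fell (50 and 4 adjusted over the list alone, median 0.35, adjusted p = 1.16e-08, and adjusted p = 0.737 with an estimated correlation). Rpl13a, Rps27 and Rpl37a rose by 1.09 (0.65 without Mll2 KO 2), 0.77 and 0.69 on the log2 scale, while Rpl17 fell by 1.07. Of 20 genes of the integrated stress and unfolded protein response, 9 rose and 2 fell (12 and 2 adjusted over the list alone, median 0.43, adjusted p = 0.00741, and adjusted p = 0.704 with an estimated correlation). Ddit3, which encodes the stress-induced factor CHOP, rose from 104.4 ± 0.97 to 212.1 ± 11.6 CPM (log2 1.02 ± 0.10, adjusted p = 2.32e-06). Ddit4, an inhibitor of mTOR signalling, rose from 13.8 ± 0.51 to 41.8 ± 19.6 CPM (log2 1.59 ± 0.28, adjusted p = 0.0012, and log2 0.97 without Mll2 KO 2), and the endoplasmic reticulum chaperone gene Calr rose by 0.52 on the log2 scale. All 7 of these lists stayed past the threshold without any single library. None was past it with an estimated correlation, where 1 list had an unadjusted p under 0.05. With fry the ribosomal protein and spindle lists were not past the threshold (fry adjusted p = 0.0616 and 0.0567). The numbers higher and lower with library size alone were 63 and 1 for ribosomal protein, 13 and 1 for stress response, 3 and 12 for meiotic and 1 and 6 for heat shock genes.

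The other 21 lists were not past the threshold in Mll2 KO, with adjusted p from 0.146 to 0.99. Of 26 H3K4 methylation genes, 0 were higher and 3 lower (0 and 3 adjusted over the list alone), namely Kmt2b itself, the demethylase gene Kdm5b (log2 -1.01 ± 0.22, adjusted p = 0.0031) and Psip1 (log2 -0.32, adjusted p = 0.0184, and 0.0859 and 0.0841 without Mll2 WT 1 or 2). Of 26 genes of H2A.Z deposition and removal, 8 were higher and 2 lower (8 and 2 adjusted over the list alone). Anp32e, a chaperone that removes H2A.Z, fell from 13.6 ± 0.79 to 5.37 ± 1.06 CPM (log2 -1.34 ± 0.21, adjusted p = 0.000171). Of the TIP60 complex, the acetyltransferase gene Kat5 fell by 0.77 and Epc1 rose by 0.68 on the log2 scale (0.34 without Mll2 KO 2). Of 30 meiotic resumption genes, 2 were higher and 5 lower (1 and 3 adjusted over the list alone), and 6 and 1 with library size alone. The cyclin genes Ccnb3 and Ccna2 moved apart, with log2 differences of -0.86 ± 0.14 and 0.66 ± 0.12. Among 28 subcortical maternal complex and maternal-effect genes, 1 was higher and 8 lower (1 and 8 adjusted over the list alone). Nlrp9b and Ago2 of that list fell by 0.95 and 0.88, and it was past the threshold without Mll2 WT 1 (adjusted p = 0.0143) or Mll2 KO 2 (adjusted p = 0.000822). Of 30 mRNA storage and decay genes, 2 were higher and 7 lower (2 and 7 adjusted over the list alone). Btg4, which promotes maternal mRNA decay, fell from 3399 ± 442 to 2015 ± 375.7 CPM (log2 -0.75 ± 0.13, adjusted p = 0.000612). This list was past the threshold only without Mll2 KO 2 (adjusted p = 0.0394). The splits with library size alone were 3 and 2 for H3K4 methylation, 3 and 6 for the maternal complex list and 5 and 5 for mRNA storage and decay.

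For the remaining lists in Mll2 KO, the numbers higher and lower, again with those adjusted over the list alone in brackets, began with 4 and 2 of 17 oocyte transcription factors (4 and 2), 3 and 1 of 15 histone variant genes (3 and 1), and 2 and 1 of 24 core histone genes (0 and 1). DNA methylation and KRAB repression genes had 5 and 5 of 26 (5 and 5), Polycomb genes 6 and 5 of 28 (6 and 5), developmental regulators 3 and 5 of 43 (3 and 3), genes of the 2-cell stage 7 and 3 of 18 (9 and 3), and imprinted genes 4 and 3 of 29 (4 and 3). The p53 pathway list had 4 and 2 of 26 (4 and 2), oxidative phosphorylation 9 and 7 of 80 (8 and 6), glycolysis 4 and 1 of 17 (4 and 1), cholesterol synthesis 5 and 4 of 21 (5 and 4), and spermatogenic genes 2 and 6 of 21 (2 and 6). Markers of other cell types had 4 and 4 of 16 for granulosa and cumulus cells (5 and 4), 2 and 2 of 9 for theca and stroma (2 and 2), and 3 and 1 of 7 for blood, immune and endothelial cells (3 and 1). The scaling mattered here too. Oxidative phosphorylation genes had 21 higher and 4 lower with library size alone, glycolysis 7 and 1, DNA methylation and KRAB repression 7 and 3, Polycomb genes 6 and 3, developmental regulators 4 and 3, histone variant genes 6 and 0 and oocyte transcription factors 4 and 0. Single genes that moved within these lists included the apoptosis gene Bax, from 25 ± 0.00 to 6.43 ± 0.44 CPM (log2 -1.96 ± 0.16, adjusted p = 2.3e-07). The imprinted cell cycle inhibitor gene Cdkn1c rose from 9.86 ± 0.18 to 27.4 ± 0.65 CPM (log2 1.48 ± 0.19, adjusted p = 3.09e-05), and Mael, a piRNA pathway gene, fell from 107.8 ± 2.64 to 32.6 ± 5.81 CPM (log2 -1.72 ± 0.13, adjusted p = 1.08e-07).

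The series sets the mutants side by side, and the overlap of their changes was tested with Fisher's exact test (two-sided), in which genes are not independent replicates. By this exact test 988 genes were higher in both comparisons against 471.1 expected for independent lists (odds ratio 3.65, 95% interval 3.32 to 4.01, exact p = 3.18e-155). The same test gave 740 lower in both against 312.6 (odds ratio 4.04, 3.64 to 4.49, exact p = 3.13e-141). Opposite changes were fewer than expected, with 284 genes higher under the DKO label and lower in Mll2 KO (529.7 expected) and 116 the other way (278 expected). Shared changes were ranked under the naming rule, which asks for 10 CPM or more in the higher group of each line. Under that limit the genes with the largest shared increases were Mt1, Prpf39, Ccl2, the keratin gene Krt73 (log2 2.10 ± 0.17 and 1.69 ± 0.17 under the DKO label and in Mll2 KO), the netrin receptor gene Dcc (log2 2.15 ± 0.38 and 2.06 ± 0.39) and Ddit4 (log2 1.38 ± 0.30 and 1.59 ± 0.28). The Mll2 KO value of Dcc had an adjusted p of 0.0545 and 0.111 without Mll2 KO 1 or 2, and that of Ddit4 was 0.97 without Mll2 KO 2. Ccl2 rose by 3.62 ± 0.30 and 2.65 ± 0.29, and Prpf39 by 1.97 ± 0.16 and 3.2 ± 0.16. Under the same limit the largest shared decreases were in Zfp788, Commd8, Efcab7, Ckap2l (log2 -3.11 ± 0.27 and -4.48 ± 0.29), Zfp959 (log2 -2.99 ± 0.31 and -4.48 ± 0.38) and Esd, an esterase gene (log2 -2.87 ± 0.16 and -3.90 ± 0.17). Esd went from 79.7 ± 1.89 to 10.9 ± 1.79 CPM under the DKO label and from 50.4 ± 2.83 to 3.37 ± 0.61 CPM in Mll2 KO. Of the targeted genes, H2afz was among those higher in both.

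Across all 16847 genes the log2 fold changes of the mutants correlated with r = 0.341 (Spearman 0.318). The value was 0.12 without a filter on low counts and 0.152 with DESeq2, both taken over all genes with any count. Of the 16847 genes, 60.4% had the same sign, and r was 0.667 over the 2128 genes called in both. Choosing genes called in both leaves out small changes in either comparison, which can by itself raise r. Differences between replicates, taken as a background, gave r from -0.056 to 0.005. The number higher in both was 494 and 533 without H2A.Z control 1 or 2, 527 and 590 without DKO 1 or 2, 549 and 333 without Mll2 WT 1 or 2, and 636 without Mll2 KO 2. The number lower in both was 450 without H2A.Z control 1, 479 and 485 without DKO 1 or 2, and 1424 and 1135 without Mll2 KO 1 or 2.

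**Figure D2:**
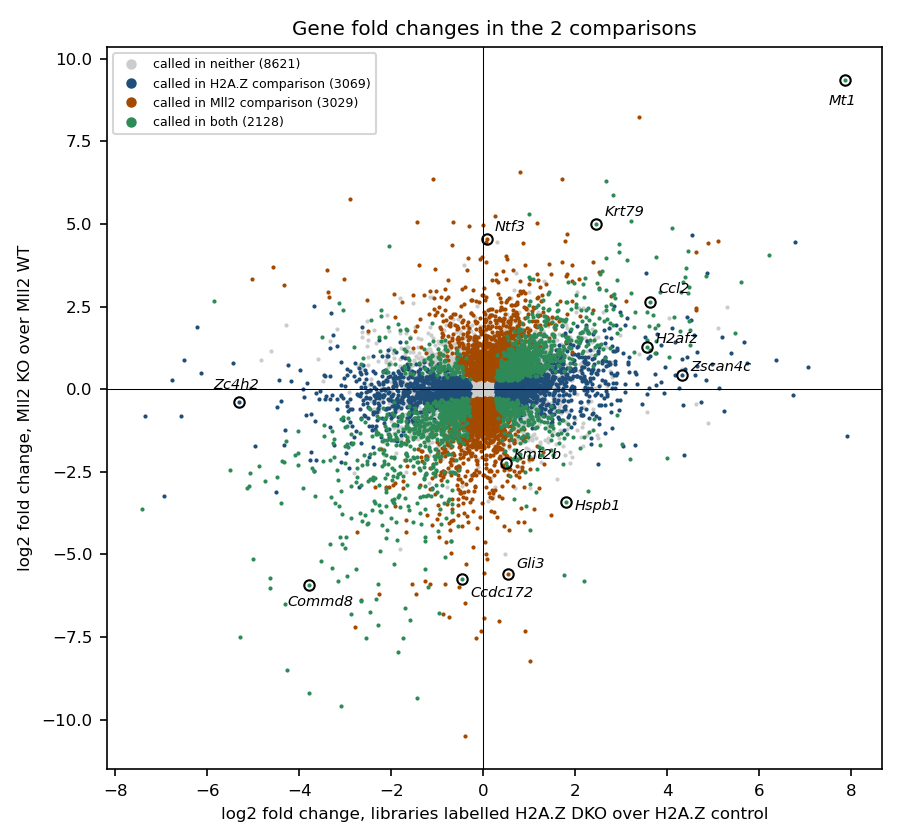
Log2 fold change of the libraries labelled DKO over control (x axis) against Mll2 KO over WT (y axis) for 16847 genes, coloured by the comparison in which they were called, with named genes circled. Of these, 2128 genes were called in both comparisons, and Mt1 lies at log2 7.87 and 9.36.

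The difference between the effects was tested directly by an interaction contrast, which called 3291 genes, 2165 with a higher log2 fold change under the DKO label and 1126 with a higher one in Mll2 KO. Differences were ranked under the naming rule, among genes at 10 CPM or more in any group. Under that limit the largest differences with the higher value under the DKO label were in Gli3 (6.14 ± 0.61), Gca, a calcium-binding grancalcin gene (5.36 ± 0.43), Epha7, an ephrin receptor gene (5.31 ± 0.74), Ccdc172 (5.28 ± 0.23), Hspb1 (5.21 ± 0.41) and Tmem47 (5.05 ± 0.34). The largest the other way under that limit were in Zc4h2 (-4.93 ± 0.46), Ntf3 (-4.45 ± 0.57), Zfp85 (-3.88 ± 0.33), Nicn1 (-3.54 ± 0.38), Speer4a (-3.46 ± 0.50) and Kcnmb2, a potassium channel subunit gene (-3.4 ± 0.32). Hspb1 rose under the DKO label (log2 1.80 ± 0.24) and fell in Mll2 KO, as did Gca (log2 2.27 and -3.09) and Epha7 (log2 3.2 and -2.11). The fall of Epha7 had an adjusted p of 0.152 and 0.12 without Mll2 WT 1 or Mll2 KO 2, and was log2 -3.45 without Mll2 KO 1. The difference of Gli3 had an adjusted p of 0.0534 without Mll2 KO 1. The share of these calls with the higher value under the DKO label was 65.8% with the scaling used and 37% with library size alone, under which the median of all genes moved from 0.12 to -0.12. The count was 2182 and 1639 without H2A.Z control 1 or 2, 1924 and 2040 without DKO 1 or 2, and 1733 without Mll2 WT 2.

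The lists that differed between the mutants were led by meiosis, oocyte and heat shock genes. Meiotic cohesin, synapsis and recombination genes had higher log2 fold changes under the DKO label in 11 of 29 and lower in 3 (12 and 3 adjusted over the list alone, adjusted p = 0.0184). The same held for zona pellucida list genes in 7 of 15 and lower in 0 (8 and 0 adjusted over the list alone, adjusted p = 0.0184), and for heat shock genes in 4 of 14 and lower in 0 (8 and 0 adjusted over the list alone, adjusted p = 0.0184). Genes of the 2-cell stage differed in 5 of 18, all with the higher value under the DKO label (5 adjusted over the list alone, adjusted p = 0.0206). The filter can raise this difference too, since members with few counts elsewhere could be tested through the libraries labelled DKO. Stress response genes had the higher value in Mll2 KO in 5 of 20 and in 0 the other way (5 adjusted over the list alone, adjusted p = 0.0464). Subcortical maternal complex genes had 8 and 0 of 28 (10 and 1 adjusted over the list alone, adjusted p = 0.0488) and histone variant genes 5 and 1 of 15 (8 and 2 adjusted over the list alone, adjusted p = 0.0488). The histone variant list includes the targeted genes H2afz and H2afv and was not tested without them. Each of these 7 lists had an adjusted p = 0.611 with an estimated correlation, under which 0 lists had an unadjusted p under 0.05. With fry the maternal complex and stress response lists were not past the threshold (fry adjusted p = 0.0557 and 0.0689). Ribosomal protein genes, with 49 higher under the DKO label and 46 in Mll2 KO, differed in 6 and 1 of 80 (adjusted p = 0.866), and 0.0186 without Mll2 KO 1. Lists gained without a library were the APC/C list without H2A.Z control 1, DKO 2 or Mll2 KO 1 (adjusted p = 0.0306, 0.0477 and 0.022), DNA methylation and KRAB genes without H2A.Z control 1, DKO 2 or Mll2 KO 2 (0.0356, 0.0477 and 0.0111) and oxidative phosphorylation without H2A.Z control 1, DKO 1 or Mll2 WT 1 (0.039, 0.0253 and 0.0169). Without Mll2 KO 2, the mRNA storage, H3K4 methylation and Polycomb lists were gained as well (adjusted p = 0.0249, 0.0111 and 0.0111). Only the meiotic and heat shock lists stayed past the threshold without any single library. The zona pellucida list was not past it without Mll2 WT 2 (adjusted p = 0.131), nor the 2-cell list without H2A.Z control 2, DKO 2, Mll2 WT 1 or Mll2 KO 2 (0.0744, 0.0519, 0.0515 and 0.067). The histone variant list was not past it without H2A.Z control 2, DKO 2 or Mll2 WT 2 (0.0621, 0.0519 and 0.131). The maternal complex list was not past it without H2A.Z control 2, DKO 2, Mll2 WT 2 or Mll2 KO 1 (0.0814, 0.0519, 0.489 and 0.396), nor the stress response list without H2A.Z control 2, DKO 1, Mll2 WT 1, Mll2 WT 2 or Mll2 KO 2 (0.0814, 0.107, 0.0515, 0.0525 and 0.0647).

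**Figure D3:**
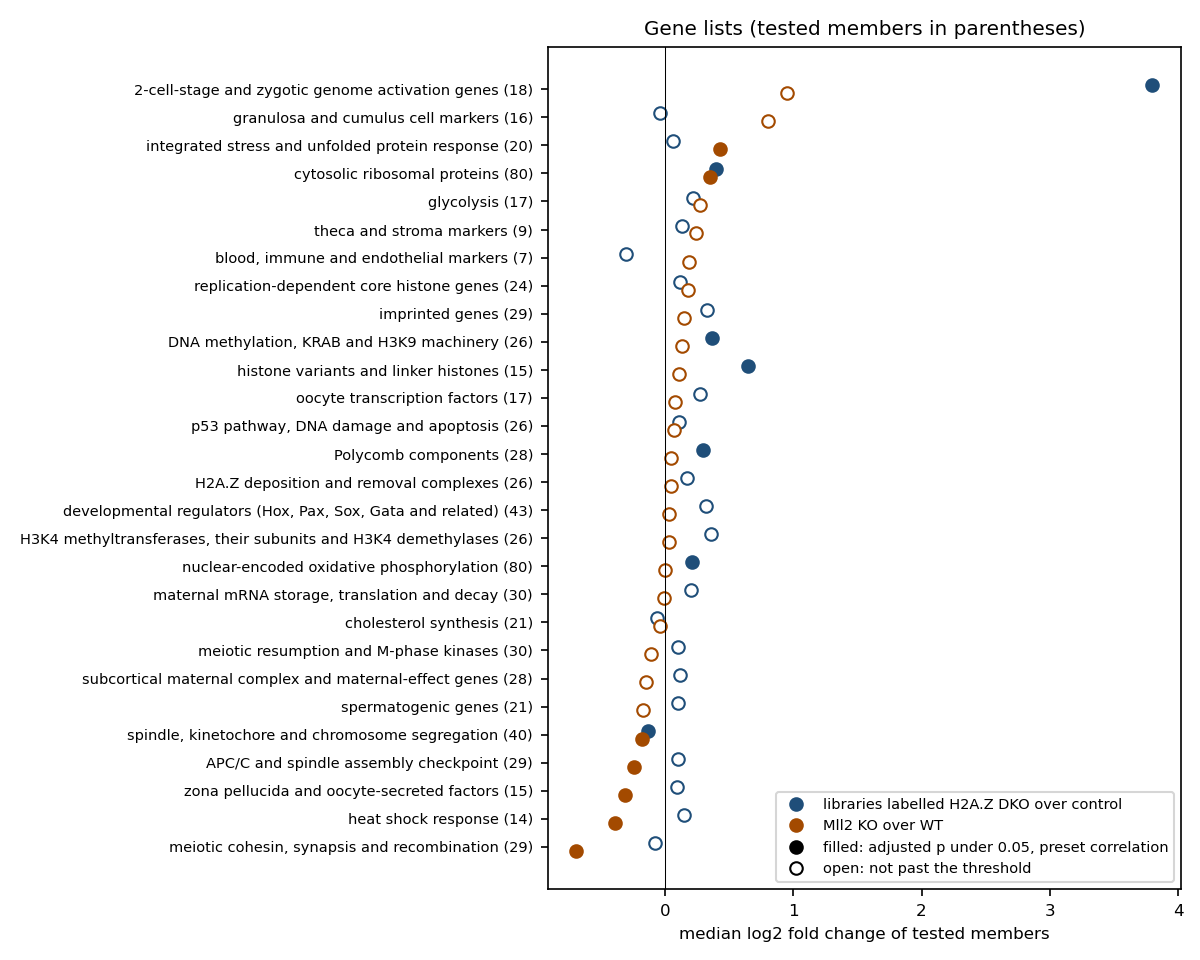
Median log2 fold change of each gene list under the DKO label over control and in Mll2 KO over WT, with filled points for lists with a camera adjusted p under 0.05. The 2-cell list has medians of 3.80 and 0.95 over its 18 tested members, which the filter on low counts can raise, and the meiotic list -0.08 and -0.69. With library size alone as the scaling, the medians of 6 lists that were not past the threshold change sign under the DKO label, and in Mll2 KO those of the mRNA storage (-0.01 to 0.12), meiotic resumption (-0.11 to 0.01) and cholesterol synthesis (-0.04 to 0.08) lists.

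The controls of the 2 lines were compared as a background. H2A.Z controls and Mll2 WT differed in 7464 genes (44.3% of those tested), with 3200 higher in the H2A.Z controls and 4264 lower, of which 989 and 1928 differed more than 2-fold. H2afz was higher in the H2A.Z controls by 1.93 on the log2 scale (adjusted p = 2.69e-07) and Kmt2b lower by log2 -1.53. No comparison here sets a mutant of one line against a control of the other.

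Fold changes were also set against expression level, in 10 bins of genes set in the controls of the other line. In Mll2 KO the median log2 fold change was 0.48 in the lowest bin, with 226 genes higher and 43 lower, and -0.17 in the highest, with 106 higher and 526 lower. The difference was -0.65 (SD over pairs of libraries 0.11), and -0.38 when the bins were set from all 8 libraries. Under the DKO label the medians were 0.38 in the lowest bin (217 higher and 67 lower) and 0.14 in the highest (480 higher and 95 lower). Their difference of -0.24 (SD 0.099) reversed to 0.08 with those bins. It came from the lowest bin, since the medians of bins 2 to 10 lay between 0.084 and 0.144. Genes of the lowest bin had a median of 0.301 CPM in the reference controls (0.332 CPM for Mll2 KO). Such genes could pass the filter through other libraries, the mutants among them, which can raise the median of that bin. In Mll2 KO the medians still went from 0.138 in bin 2 to -0.17 in bin 10.

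**Figure D4:**
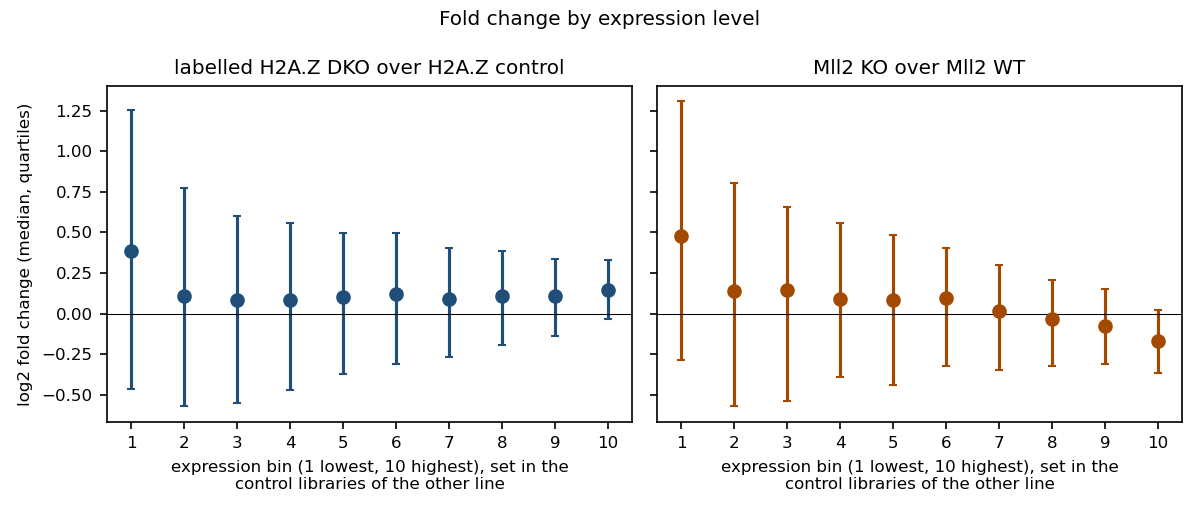
Median and quartiles of the log2 fold change in 10 bins of expression level, for the libraries labelled DKO over control and for Mll2 KO over WT, with bins set in the controls of the other line. The Mll2 KO medians run from 0.48 in the lowest bin to -0.17 in the highest, and the difference between highest and lowest bin under the DKO label turns from -0.24 to 0.08 with bins set from all 8 libraries. The Mll2 KO difference goes from -0.65 to -0.38 with those bins. The median of the lowest bin can be raised by the filter on low counts.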

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

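No test in this part was chosen after its result was seen. The effects of the mutants were compared within the same contrast, mutant against control, and the interaction contrast found 3291 genes whose log2 fold change differed between the libraries labelled DKO and the Mll2 KO libraries. H2afz and H2afv were higher under the DKO label, so each direction below is that of the label. The count is listed here because the test is one of the difference itself. It does not rank causes, and since the lines differed in 44.3% of genes already between their controls, no biological explanation of the difference was tested.

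Among genes at 10 CPM or more in any group, ranked under the naming rule, those with the largest differences are given here. They are those with the higher log2 fold change under the DKO label, Gli3 (6.14), Gca (5.36), Epha7 (5.31), Ccdc172 (5.28), Hspb1 (5.21) and Tmem47 (5.05), and those with the higher one in Mll2 KO, Zc4h2 (-4.93), Ntf3 (-4.45), Zfp85 (-3.88), Nicn1 (-3.54), Speer4a (-3.46) and Kcnmb2 (-3.4). For Gca, Epha7, Hspb1 and Kcnmb2 the mutants moved in opposite directions, each past the test. Kcnmb2 had log2 changes of -2.65 under the DKO label and 0.75 in Mll2 KO, the second not past the test without Mll2 WT 1 (adjusted p = 0.0618) or Mll2 WT 2 (adjusted p = 0.0641), and the fall of Epha7 in Mll2 KO was not past it without Mll2 WT 1 (adjusted p = 0.152) or Mll2 KO 2 (adjusted p = 0.12). In Ntf3 the difference came from the rise in Mll2 KO (log2 4.53, against 0.08 under the DKO label). In Gli3, Ccdc172 and Tmem47 the difference came mainly from the fall in Mll2 KO, with log2 changes under the DKO label of 0.53, -0.46 and 0.07. In Zc4h2, Zfp85, Nicn1 and Speer4a it came mainly from the fall under the DKO label, with log2 changes in Mll2 KO of -0.38, 0.42, -0.10 and 0.56, none past the test.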

How the results depend on the processing

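Offsets for GC content and length were chosen after the data had been seen, and the other alternatives before. No call of a named gene changed direction in the alternatives that tested it or without any library, while single calls were lost, most often without H2A.Z control 1 or Mll2 WT 2 (40 of 405 gene results each), and 26 with library size alone as the scaling. The 405 gene results include those not called with all 8 libraries, which could not be lost, so a share of 405 understates the loss of calls. Relative log expression factors, a mean of at least 5 CPM and the GC and length offsets kept every count of genes within 1.5 times. Planned removal of mitochondrial and ribosomal RNA genes was not run, since 0 of them were tested. Without a library an arm holds 1 sample, which is assumed to vary like the other groups. With 2 libraries per group, the interaction contrast recovered 31.3% of simulated 2-fold differences, a rate that need not hold for the data, where far more genes changed than in the simulation.

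The cause was not tested for the following changes, except that an added limit lowers counts by its construction. With the absolute log2 fold change over 1, the counts were 981 higher and 987 lower under the DKO label, 996 and 1134 in Mll2 KO, 1809 in the interaction contrast, 2917 between controls, and 314 lower and 243 higher in both. With library size alone, 2063 were higher under the DKO label. With each line alone, 3485 were lower under the DKO label and 649 higher in both. The correlation of fold changes was 0.12 without a filter on low counts and 0.152 with DESeq2, both over all genes with any count and not only those tested. With bins from all 8 libraries, the difference between highest and lowest bin was 0.076 under the DKO label, a reversal of direction, and -0.379 in Mll2 KO. No list was past the threshold with an estimated correlation (0, 0 and 0 in the comparisons under the DKO label, in Mll2 KO and between them), and fry gave 11, 7 and 11. The fry counts do not cover the same lists. With fry the spindle list was lost in both mutant comparisons. The ribosomal protein list was lost in Mll2 KO, where glycolysis and spermatogenic genes were gained. Between the mutants the maternal complex and stress response lists were lost and others gained. With a replicate block, which the labels do not support, the counts were 3120 higher and 1868 lower under the DKO label, 2305 and 2663 in Mll2 KO, 3119 in the interaction contrast and 4999 between controls, with 7, 7 and 5 lists.

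Without one library at a time, the ranges were 1496 to 3188 higher and 1115 to 3381 lower under the DKO label, 990 to 3351 and 1691 to 3468 in Mll2 KO, 1639 to 4639 in the interaction contrast, 5183 to 8659 between controls, 333 to 1379 higher and 450 to 1424 lower in both, and 0.242 to 0.313 for the correlation. Lists ranged from 5 to 8, 7 to 9 and 3 to 10.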

Other observations

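The gene families below, the exchange of labels, the even level of Mt1 and the markers of other cell types were tested only after the results were seen. Numbered zinc finger genes (Zfp), many of which encode KRAB repressors of transposons, were lower in both mutants, as labelled, more often than other genes. Under the DKO label 93 of 286 were lower, 32.5% against 11.1% of other genes (odds ratio 3.86, 95% interval 2.97 to 5, Fisher's exact p = 9.57e-22). In Mll2 KO 101 were lower, 35.3% against 15.9% (odds ratio 2.89, 2.24 to 3.72, exact p = 1.99e-15), and 60 were lower in both. If the H2A.Z labels were exchanged, 25 would be lower and 93 higher in the H2A.Z mutant. With offsets for GC content and length the odds ratios were 3.09 and 2.21, and with each line fitted alone 2.82 and 3.24. Genes are not independent here, and related zinc finger genes can share reads.

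X-linked genes were lower in Mll2 KO in 150 of 528, 28.4% against 16.1% of other genes (odds ratio 2.07, 1.7 to 2.52, exact p = 2.51e-12), and the odds ratio was 1.78 with GC and length offsets and 2.65 with the line alone. Under the DKO label the share was 15% against 11.5% (odds ratio 1.36, exact p = 0.0155), and the odds ratio was 1.19 with the offsets (exact p = 0.151). With the H2A.Z line fitted alone the share was 29% against 22.2% (odds ratio 1.43, exact p = 0.000621). The difference between the mutants was tested directly: 116 of 528 X-linked genes had a significantly higher log2 fold change under the DKO label than in Mll2 KO, 22% against 12.7% of autosomal genes (odds ratio 1.93, exact p = 7.69e-09). If the H2A.Z labels were exchanged, 90 of 528 (17%) would be lower in the H2A.Z mutant, and this test of the difference would no longer apply. Of 10 Xlr genes, an X-linked repeated family, 8 were lower in Mll2 KO (median log2 -3.97) and 6 under the DKO label (median log2 -0.77). Of 14 Nlrp genes, which include maternal-effect genes, 5 were lower in Mll2 KO and 1 under the DKO label, and the share in Mll2 KO was not past the exact test against other genes (p = 0.0622). All 4 tested Zscan4 genes were higher under the DKO label and 2 in Mll2 KO (Zscan4a and Zscan4d), and 3 of 4 Usp17l genes were higher in each. The Mll2 KO calls of Zscan4 genes were lost without Mll2 WT 2 (adjusted p = 0.205 for Zscan4a and for Zscan4d) or Mll2 KO 1 (0.184 and 0.253), that of Zscan4a also without Mll2 WT 1 (0.0637) and that of Zscan4d without DKO 2 (0.0503), and the log2 value of Zscan4d went from 0.97 to 0.64 and 0.43 without Mll2 WT 2 or Mll2 KO 1. Within 5 Mb of H2afz, H2afv and Kmt2b, 32.6%, 26.8% and 27.3% of genes were called in the comparison that targets each, against 30.9%, 30.9% and 30.6% of all genes.

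H2afz and H2afv were higher, not lower, in the libraries labelled DKO. An exchange of labels between control and DKO libraries stays open: those labelled control had more H2afz than Mll2 WT by 1.93 and more H2afv by 0.30 (adjusted p = 0.025) on the log2 scale, and the rise of Mt1 pairs the DKO label with Mll2 KO, all against an exchange, but controls of the lines differ in 44.3% of genes and a modified allele need not lower the count. Transcripts of such an allele that keeps counted exons stay open too, because the log2 difference of 3.56 is over the whole gene and the counts hold no exons. Reads shared with copies of H2afz cannot be told apart from it either: Gm8203, identical to H2afz over 387 bases, rose by 3.08, with counts equal to 0.77% of those of H2afz in the libraries labelled DKO, while Tmcc1, 99.9% identical over 682 bases, moved by 0.94 (adjusted p = 0.0755 and 0.0539 without H2A.Z control 2 or DKO 2) with counts equal to 4.49%. Counts of Tmcc1 did not follow H2afz: they were 666 and 503 in Mll2 WT but 157 and 173 in the H2A.Z controls, where H2afz was higher. The change of Tmcc1 and its share of counts therefore do not measure a copy of H2afz. No copy of H2afv passed the search limits, so reads shared with such copies concern H2afz only. A change in transcription of the intact genes was not tested.

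Mt1 was 234-fold and 657-fold higher in the libraries labelled DKO and in Mll2 KO. A response of the metallothionein genes to metal or stress is argued against under the DKO label, where its neighbour Mt2 changed by 0 (SE 0.52), and stays open in Mll2 KO, where Mt2 moved by 1.78 (SE 0.69, adjusted p = 0.0644). Both values rest on few Mt2 counts. There were 68 and 15 in the H2A.Z controls, 36 and 51 under the DKO label, 9 and 8 in Mll2 WT, and 29 and 29 in Mll2 KO. Mt1 had 34900 and 34845 counts in Mll2 KO. A candidate explanation is RNA of a transgene that carries Mt1 sequence, since the Mt1 polyadenylation region is used in some expression constructs, but the labels name no transgene. The even level of Mt1 in the 4 mutant libraries (highest 1.18 times the lowest) prompted this idea, so it lends it no support, and the idea stays open until reads along the gene are seen.

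The log2 fold changes of the mutants went together across genes, less so over all genes with any count (r = 0.12 without a filter on low counts and 0.152 with DESeq2). With the H2A.Z labels exchanged r would be -0.341, with 116 genes higher and 284 lower in both, so the direction of the pattern rests on the labels. A trend with GC content or transcript length does not account for the correlation, since r was 0.345 before and 0.334 after offsets for both over 14638 genes. Neither does expression level, since the median r within 10 bins of expression was 0.371. A shared change in other cell types stays open, although 0 of 3 marker lists had medians that moved the same way by 0.5 or more. Under the DKO label and in Mll2 KO, the summed CPM of the granulosa list went from 650.3 to 696.8 and from 834.4 to 605.7. That of the theca list went from 57.3 to 63.3 and from 84.6 to 53.2. That of the blood, immune and endothelial list went from 74.8 to 75.9 and from 83.4 to 95.3. Members went both ways, and the granulosa marker Fshr rose in both mutants, by 4.36 and 3.23 on the log2 scale. A response of oocytes common to both mutants stays a hypothesis, and other differences between mutant and control animals, such as age or strain, were not tested because the labels do not give them.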
